A study of Arabidopsis thaliana with 144 samples.

How the data were processed

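RNA-seq gene counts of whole-seedling libraries of Arabidopsis were analysed, from poly(A) RNA and, per the labels, non-stranded, so that reads of overlapping genes on opposite strands share a count. The genotypes were Col-0, phf1 and phr1 phl1, the pre-treatments of 7 days were 5 µM Pi, 1 mM Pi or 1 mM phosphite, and the following 12 days were on 50 or 625 µM Pi without sucrose, with or without SynCom. Each of the 36 groups had 4 replicates, 2 from each of experiments A and B.

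The deposited values are counts per gene, 1 column per library, which the authors did not normalise. For these counts the authors name CASAVA 1.8, cutadapt 1.3, TopHat2 2.1.1 and HTSeq 0.6.1p1 with the TAIR10 build, without saying how each was used. The table lists 27206 nuclear genes, of which 25170 have at least 1 count. Gene symbols came from a RefSeq table in which 487 of these loci are not listed and keep their locus identifier, and no coordinates were used.

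Groups, comparisons, tests, 21 gene lists and alternatives were fixed before the data were examined. Genes were filtered with filterByExpr over the 36 groups (minimum count 10), which left 19321, and libraries were scaled by TMM (factors 0.82 to 1.19). A single quasi-likelihood model in edgeR 4.0.16 (R 4.3.3) held a mean for each group and a term for experiment, and 20 contrasts averaged over the pre-treatments (12 libraries per arm for Pi and SynCom, 24 for genotype, 16 for pre-treatment, groups of 4 for the pre-treatment interactions). Genes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast were called. Values for experiments A and B came from separate fits, and the difference between them from a fit with means for each group in each experiment.

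The lists covered Pi signalling and transport, Pi scavenging, membrane lipid remodelling, salicylic acid, jasmonate, pattern-triggered immunity, glucosinolates, flavonoids, iron deficiency, ferritins, nitrate, sulfate, photosynthesis, root hairs, root endodermis, senescence, cell division, abscisic acid, heat shock, touch and the circadian clock. They were tested with camera in edgeR (preset correlation 0.01, and with an estimated correlation) and with fry, adjusting over all 420 tests, of which camera passed 160, camera with an estimated correlation 30 and fry 105. Fry asks whether a list's genes move one way on balance and compares it with no other genes. For each list, members were also counted with p values adjusted over the list alone.

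The index is the mean over 25 Pi starvation genes of log2 CPM (prior count 2) minus each gene's mean, and its genes are also members of the Pi and lipid lists. Its 12 differences were tested by permuting libraries within pre-treatments (100000 resamples, 2-sided; the smallest p they gave was 2e-05), and within single pre-treatments by exact permutation tests of 4 against 4 libraries (70 splits).

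Named genes were drawn by a rule. In each comparison up to 4 members with the smallest p of each list described were eligible. So were up to 5 genes with the largest change in each direction. These had to be called, average at least 5 CPM and go the same direction in both experiments. Eligible too were the targeted genes in genotype comparisons and 10 fixed markers. The markers were IPS1, SPX1, PHT1;4, SQD2, PAP17 and PPsPase1 for Pi, and PR1, VSP2, MYB75 and CYP79F1 for SynCom and genotype. Not every eligible gene is given: MYB75 and CYP79F1 appear in only some comparisons and VSP2 in none.

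Alternatives were each experiment alone, no experiment term, the replicate numbers as block, leaving out replicate A1, A2, B1 or B2, other filters on low counts, the size factors of DESeq2 in edgeR, only the compared libraries in the fit, DESeq2 1.42.0 (Wald test) and limma-voom with quality weights (limma 3.58.1). For the index they were a prior count of 0.5, the median, other size factors and narrower permutation strata. Fits without 4 and without 6 libraries in doubt were chosen after seeing the data. Replicate numbers did not pair libraries across groups (mean r of residuals 0.009 over 630 pairs of groups in each experiment), so libraries were treated as unpaired.

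Libraries held 0.72 M to 10.7 M counts, the 10 highest genes took 3.5 to 11.9% of them, and the residual SD within groups was 0.23 to 0.95 on the log2 scale (median 0.38). No library held the same counts as another of its group (216 pairs compared). The chi-square of their count differences per degree of freedom was 1.36 for the closest pair, against a median of 17.8. A shared source of the closest pair is therefore not excluded, and pairs across groups were not compared. Tested on simulated data in place of SynCom against no bacteria in Col-0 at low Pi, the model recovered 64.2% of 67 genes changed 1.5-fold, 86.6% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, with 8 false calls among 19121 unchanged genes. Of 200 random lists without change camera passed 1%, or 1.5% with an estimated correlation, and fry 5.5%. Counts of the simulated genes were drawn independently and without effects of experiment. These rates therefore do not cover correlated genes or effects that differ between A and B. A simulated shift of the index by 1 was recovered as 1.07. Python 3.11.15 and matplotlib 3.10.9 drew the figures.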

Results

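Arabidopsis seedlings of the wild type Col-0 and of the mutants phf1 and phr1 phl1 were profiled by RNA-seq of whole seedlings. PHF1 lets PHT1 phosphate transporters leave the endoplasmic reticulum, and PHR1 and PHL1 are the MYB transcription factors that switch on most genes of the phosphate (Pi) starvation response. Seedlings spent 7 days on 5 µM Pi (−P), 1 mM Pi (+P) or 1 mM phosphite (+Phi), an analogue of Pi that plants take up but do not metabolise. The next 12 days were at 50 µM Pi, called low Pi here, or at 625 µM, called high Pi, alone or with a synthetic community of bacteria (SynCom). The 36 combinations had 4 libraries each, 2 from experiment A and 2 from experiment B. The libraries held 0.72 M to 10.7 M gene counts (median 4.1 M), with medians of 4.21 M in A and 3.8 M in B. Of 27206 genes, 19321 passed the filter on low counts. Experiment was the main axis of variation, since the first principal component held 37.5% of the variance and experiment accounted for 75.4% of that component. Many effects are therefore given with their values in experiments A and B, written after the pooled value as (A, B) or [A, B], and the others as the pooled value alone. Errors of log2 fold changes are standard errors, those of CPM and index means are SDs, and calls are from edgeR's quasi-likelihood test at an adjusted p under 0.05.

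The targeted genes were examined first. PHR1 (AT4G28610) averaged 30.6 ± 9.93 CPM in the 48 libraries labelled phr1 phl1, against 68.3 ± 10.3 in Col-0 and 61.8 ± 10.6 in phf1. PHL1 (AT5G29000) was higher in phr1 phl1, at 72 ± 44.5 CPM against 15.7 ± 9.16 in Col-0 and 14.8 ± 9.61 in phf1, and the phr1 phl1 mean was 105 ± 40.1 in A and 38.7 ± 11 in B (n = 24 each). PHF1 (AT3G52190) averaged 19.4 ± 12 CPM in phf1, 28.6 ± 32.4 in Col-0 and 16.2 ± 6.73 in phr1 phl1, so its level did not separate phf1 libraries from the rest. In 4 libraries of experiment A the ratio of PHR1 to PHL1 went against the genotype label. The library labelled Col-0, +Phi, low Pi, no bacteria, A1 had 27.7 CPM of PHR1 and 74.3 of PHL1, and the library labelled phr1 phl1, +P, high Pi, SynCom, A1 had 83.2 and 20.4. The libraries labelled phf1, high Pi, SynCom had PHL1 at 75.2 CPM (−P, A2) and 31.3 CPM (+Phi, A1). Their PHR1, at 53.8 and 48.7 CPM, lay within the range of phf1 libraries (39.2 to 86.5 CPM). All 4 were kept under their labels, together with a library labelled Col-0, +P, high Pi, no bacteria, B1 of high residual spread and the shallowest library (phr1 phl1, −P, low Pi, SynCom, A1). Counts without these 6 libraries are given where they differ by more than 1.5 times.

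**Figure D1:**
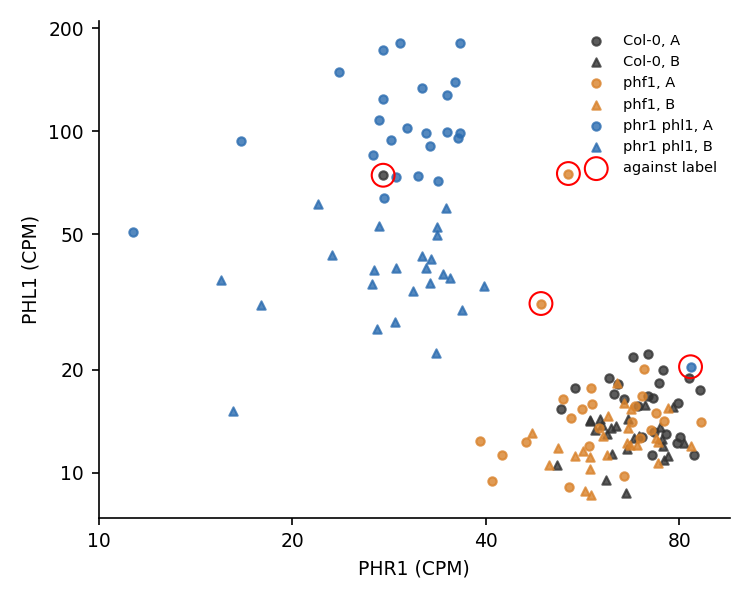
PHL1 against PHR1, in CPM on log axes, 1 point per library, coloured by the labelled genotype, with the 4 libraries whose PHR1 to PHL1 ratio goes against the label circled. Libraries labelled phr1 phl1 averaged 30.6 CPM of PHR1 and 72 CPM of PHL1, and Col-0 libraries 68.3 and 15.7.

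The Pi starvation index, the mean centred log2 CPM of 25 Pi starvation genes, differed between the conditions. In Col-0 it averaged −1.71 ± 0.13 at high Pi without bacteria, −1.69 ± 0.25 at high Pi with SynCom, −0.54 ± 0.63 at low Pi without bacteria and 2.81 ± 1.05 at low Pi with SynCom (n = 12 each). SynCom thus raised the index of Col-0 at low Pi by 3.35 (3.52, 3.17; adjusted p = 7.2e-05, permutation test), and the difference at high Pi was 0.03 (0.13, −0.07; adjusted p = 0.752). In phf1 the index without bacteria was already 1.34 ± 1.13 at low Pi and 0.01 ± 0.48 at high Pi. SynCom raised it by 1.54 at low Pi in that mutant (1.15, 1.94; adjusted p = 0.00139) and lowered it at high Pi (−0.60; −0.65, −0.55; adjusted p = 0.00843). In phr1 phl1 the index stayed between −1.27 ± 0.40 and 0.22 ± 0.60. Low Pi raised it by 0.96 without bacteria (1.33, 0.58) and by 1.49 with SynCom (1.3, 1.68). The SynCom difference at low Pi was 0.47 (−0.13, 1.08; adjusted p = 0.114). Low Pi raised the index in Col-0 by 1.17 without bacteria (1.3, 1.05) and by 4.49 with SynCom (4.69, 4.30), and in phf1 by 1.33 (1.83, 0.82) and 3.48. Of the 12 differences, 9 passed after adjustment. Within single pre-treatments, 18 of 36 exact permutation tests of 4 against 4 libraries reached p = 0.0286, the smallest they can give, and 0 passed after adjustment, where the smallest value was 0.0572. In Col-0 with SynCom at low Pi the index was 3.43 ± 0.94 after +P, 3.36 ± 0.44 after −P and 1.63 ± 0.41 after +Phi (n = 4 each).

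**Figure D2:**
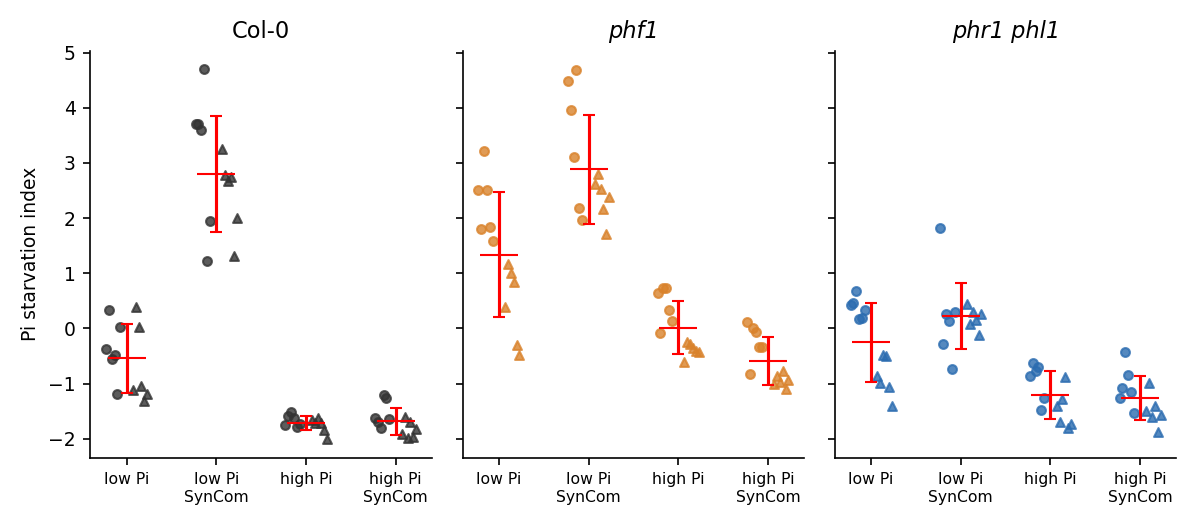
Pi starvation index (mean centred log2 CPM of 25 genes) of each library by genotype, Pi level and bacteria, with circles for experiment A and triangles for B; bars are means with SD of 12 libraries. Col-0 with SynCom at low Pi averaged 2.81 and the other 3 conditions of Col-0 lay between −1.71 and −0.54.

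Without bacteria, Col-0 seedlings on low Pi turned on a short list of Pi starvation genes. AT4 (AT5G03545), a noncoding RNA that sequesters the microRNA miR399, rose by a log2 fold change of 4.75 ± 0.38 (3.77, 4.98; adjusted p = 8.52e-19), from 6.35 ± 4.37 to 153 ± 165 CPM (n = 12 each). Its relative IPS1 (AT3G09922) rose from 0.11 ± 0.227 to 5.15 ± 6.14 CPM. SPX1 (AT5G20150), a Pi-sensing inhibitor of PHR1, rose by 2.05 ± 0.25 (1.70, 2.17), the Pi transporter PHT1;4 (AT2G38940) by 1.85 ± 0.27, and PHF1 by 0.74 ± 0.15 (0.57, 0.93). Among phosphatases, PPsPase1 (AT1G73010) rose by 3.46 ± 0.56 (3.75, 2.59) and PAP17 (AT3G17790), a purple acid phosphatase, by 1.36 ± 0.27, while the phospholipase gene PLDZ2 (AT3G05630) rose by 1.27 ± 0.27 (1.55, 0.96) and MGD3 (AT2G11810), a galactolipid synthase, by 2.21 ± 0.49 (2.87, 1.46). The sulfolipid synthase gene SQD2 (AT5G01220) had 0.56 ± 0.20 and did not pass (adjusted p = 0.183). Of 18 tested genes of Pi signalling and transport, 9 rose and 0 fell (13 rose when adjusted over the list alone; median 1.25 in A and 1.49 in B). This list's adjusted p was 1.7e-20 by camera and 0.0015 with an estimated correlation. Pi scavenging enzymes had 4 of 17 genes up (9 adjusted over the list alone) and lipid remodelling 3 of 11 (5), with camera calls lost at adjusted p = 0.232 and adjusted p = 0.238 with an estimated correlation. Sulfate deprivation genes rose in 5 of 13 (12 adjusted over the list alone; adjusted p = 0.0359 with an estimated correlation). The sulfate assimilation gene APR3 (AT4G21990) had 0.84 ± 0.21 (1.45, −0.02), but the list's median was 1.45 in A and −0.01 in B. Iron deficiency genes rose in 4 of 21 (8 rose and 3 fell adjusted over the list alone; medians 0.51 and −0.49; adjusted p = 0.784 with an estimated correlation), with BHLH38 (AT3G56970) at 1.63 ± 0.38 (2.01, −0.84) and the peptide gene IMA2 (AT1G47395) at 2.37 ± 0.49 (2.64, −0.97). Among the 15 lower genes was CPSRP54 (AT5G03940) of the chloroplast signal recognition particle (−0.46 ± 0.10 [−0.66, −0.25]). In all 76 genes were higher and 15 lower, of which 59 and 1 changed by a log2 of 1 or more. Within experiments the counts were 699 higher and 753 lower in A and 56 and 22 in B, and 273 genes differed between A and B. The count fell to 12, 27 and 58 without replicates A2, A1 and B2 and was 179 without the 6 libraries in doubt.

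With SynCom, the same change of Pi moved a large part of the transcriptome. IPS1 went from 0.0468 ± 0.112 to 175 ± 170 CPM and AT4 from 7.22 ± 4.09 to 1160 ± 598 CPM (log2 fold change 7.35 ± 0.41 [7.44, 7.23]). SPX1 rose by 5.31 ± 0.27 (5.51, 5.08), from 11.1 ± 3.97 to 485 ± 287 CPM, PHT1;4 by 4.95 ± 0.28 and PHF1 by 2.33 ± 0.15. PHR1 itself had −0.40 ± 0.11 (−0.47, −0.32). PPsPase1 rose by 8.09 ± 0.55, PECP1 (AT1G17710), a phosphatase of phosphocholine and phosphoethanolamine, by 8.14 ± 0.48, PAP17 by 3.97 ± 0.29, SQD2 by 3.39 ± 0.21 and the phospholipase C gene NPC4 (AT3G03530) by 4.91 ± 0.29. In the fixed lists 16 of 18 genes of Pi signalling and transport, 16 of 17 scavenging enzymes and 9 of 11 lipid genes rose and 0, 0 and 2 fell (16, 16 and 9 rose adjusted over the list alone), with adjusted p = 5.6e-05, 0.000235 and 0.00128 with an estimated correlation. All 19 glucosinolate synthesis genes rose, including the methionine chain elongation gene BCAT4 (AT3G19710) (3.04 ± 0.38 [2.78, 3.26]) and by CYP79F1 (AT1G16410), which turns elongated methionine into aldoximes (4.04 ± 0.66). Flavonoid genes rose in 13 of 14, among them the anthocyanin regulator MYB75 (AT1G56650) (5.51 ± 0.87) and chalcone synthase CHS (AT5G13930) (2.25 ± 0.33). The counts were 19 and 13 when adjusted over the list alone, and these camera calls were lost at adjusted p = 0.178 and adjusted p = 0.148 with an estimated correlation. Salicylic acid (SA) genes rose in 12 of 25, with WRKY54 (AT2G40750) at 1.3 ± 0.25 (0.94, 1.46) and the marker PR1 (AT2G14610) at 2.37 ± 0.85 (adjusted p = 0.0188; 0.30, 1.96), and adjusted p = 0.819 for the list with an estimated correlation (12 rose adjusted over the list alone). Sulfate genes rose in 9 of 13, including APR1 (AT4G04610) (2.08 ± 0.28). Cell division genes rose in 8 of 13, including the replication factor gene PCNA1 (AT1G07370) (1.64 ± 0.29), and root hair genes in 5 of 11, including the root hair regulator RHD6 (AT1G66470) (1.99 ± 0.28). Iron deficiency genes rose in 1 of 21 and fell in 13, such as the coumarin hydroxylase gene S8H (AT3G12900) (−3.21 ± 0.58 [−3.6, −2]) and the iron sensor gene BTS (AT3G18290) (−0.96 ± 0.19 [−1.52, −0.54]), and the ferritin gene FER3 (AT3G56090) rose by 1.19 ± 0.17. Adjusted over the list alone, 9 sulfate, 10 cell division and 5 root hair genes rose and 14 iron genes fell. With an estimated correlation the adjusted p values were 0.387 for sulfate, 0.525 for cell division and 0.456 for iron. Photosynthesis genes fell in 10 of 19 (RBCS1A (AT1G67090), the Rubisco small subunit, −0.59 ± 0.14; adjusted p = 0.739 with an estimated correlation). Clock genes went both ways, with 5 of 10 lower, such as PRR5 (AT5G24470) (−1.39 ± 0.19), and 3 higher. The abscisic acid list had 6 of 12 genes up (KIN1 (AT5G15960), a cold and drought gene, 2.85 ± 0.41), the jasmonate list 6 of 27 up and 1 down, and pattern-triggered immunity 4 of 24 up and 2 down. The small lists added the touch genes (1 of 3 up and 2 down, such as the xyloglucan enzyme gene TCH4 (AT5G57560), −1.71 ± 0.37), senescence (2 of 8 down), nitrate (1 of 8 up and 1 down) and ferritins (1 of 2 up). Adjusted over the list alone, 6, 5, 4, 1, 0, 1 and 1 genes rose in these 7 lists. In all 4283 genes were higher and 4105 lower, with 4017 and 3939 called in A and 2614 and 2483 in B. Of the called genes 98.3% had the same sign in both experiments, a share that calling on the pooled libraries raises. It was 91% even for SynCom in Col-0 at high Pi, where r across genes was 0. For Pi with SynCom 3364 of 3414 genes called in both experiments had the same direction. Across genes its fold changes in A and B correlated with r = 0.72, which treats genes as units though they are not independent. The count was 5335 without replicate A2.

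Adding SynCom to Col-0 at low Pi raised the Pi starvation genes further in both experiments. SPX1 rose by 3.24 ± 0.24 (3.86, 2.79), from 46.2 ± 33.4 to 485 ± 287 CPM, IPS1 by 4.85 ± 0.39, PHT1;4 by 3.23 ± 0.25 (3.30, 3.14), PECP1 by 5.08 ± 0.37, SQD2 by 2.86 ± 0.20 (3.25, 2.4) and NPC4 by 3.79 ± 0.26. The 3 Pi lists had 16 of 18, 16 of 17 and 9 of 11 genes up (17, 16 and 9 adjusted over the list alone), with adjusted p = 9.04e-06, 2.07e-05 and 0.000159 with an estimated correlation. Root hair genes rose in 9 of 11, among them the cell wall protein genes PRP1 (AT1G54970) (3.04 ± 0.44 [2.65, 4.40]) and LRX1 (AT1G12040) (2.11 ± 0.29 [2.48, 1.58]), but the list's median was 2.08 in A and 0.44 in B and its adjusted p was 0.0972 with an estimated correlation. All 19 glucosinolate genes rose (median 0.93 in A, 2.32 in B), such as BCAT4 (2.59 ± 0.36 [2.04, 3.25]) and the indole pathway regulator MYB34 (AT5G60890) (1.61 ± 0.22 [1.58, 1.52]), with adjusted p = 0.0653 with an estimated correlation. Other groups went apart between the experiments. PR1 had 2.05 ± 0.82 (adjusted p = 0.0527), made of −1.52 in A and 6.11 in B, and libraries without bacteria held PR1 at means between 560 and 931 CPM in A and between 0.167 and 3.58 CPM in B. Of 25 SA genes 8 rose and 18 differed between A and B (medians −0.42 and 1.74; adjusted p = 0.766 with an estimated correlation). Iron genes in the pooled fit included BHLH100 (AT2G41240) at −3.89 ± 0.54 (−4.40, 0.48) and IMA2 at −3.49 ± 0.56 (−4.08, 2.28). Of 21 iron genes 10 were lower and 1 higher (medians −1.14 and 0.3), with adjusted p = 0.489 for the list with an estimated correlation. The immunity marker FRK1 (AT2G19190), a receptor kinase, rose by 1.87 ± 0.37 (1.40, 2.45), as did 7 of 24 pattern-triggered immunity genes (adjusted p = 0.611 with an estimated correlation). Jasmonate genes went both ways, 8 of 27 up, including the regulator MYC2 (AT1G32640) (0.77 ± 0.16), and 2 down, including the defensin PDF1.2A (AT5G44420) (−3.20 ± 0.76 [−5.57, −1.26]). Among the largest decreases were UGT74E2 (AT1G05680), a glucosyltransferase of indole-3-butyric acid (−3.24 ± 0.30 [−3.07, −3.79]), and CYP81D11 (AT3G28740), a stress-induced cytochrome P450 (−2.73 ± 0.26 [−1.9, −4.08]). Root endodermis genes had a median of 1.47 in A and −1.32 in B, with 7 of 9 different between the experiments. In all 2733 genes were higher and 2487 lower, with 2879 and 2455 in A and 3239 and 3287 in B. Of 2160 genes called in both experiments, 1449 had the same direction and 711 the opposite, and 5303 genes differed between A and B.

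**Figure D3:**
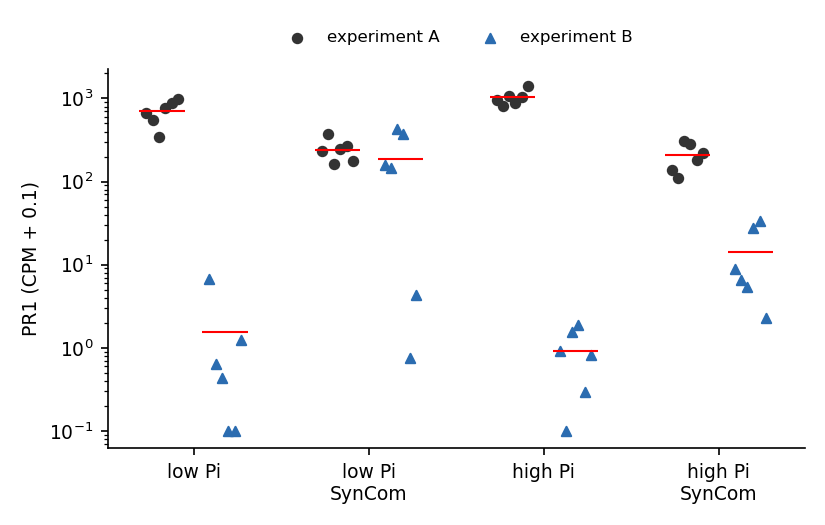
PR1 in CPM (log axis, 0.1 CPM added) in each Col-0 library by Pi level and bacteria, in experiments A (circles) and B (triangles); horizontal lines are means of the 6 libraries of an experiment. In A PR1 was high with and without SynCom, and in B it was low without SynCom, with means of 0.167 to 3.58 CPM per pre-treatment at low Pi.

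At high Pi, SynCom moved few Pi starvation genes of Col-0 and raised root hair genes. SPX1 had −0.02 ± 0.27 (0.04, −0.13) and PHT1;4 0.13 ± 0.30. Of the 18 genes of Pi signalling and transport 2 rose and 1 fell (2 and 1 adjusted over the list alone). Among them the transporter PHT1;1 (AT5G43350), which may share reads with near-identical copies, had 1.24 ± 0.27 (2.30, 0.21) and the regulator WRKY75 (AT5G13080) −1.05 ± 0.21 (−1.05, −1.11). Root hair genes rose in 9 of 11 (10 adjusted over the list alone), with PRP1 at 3.72 ± 0.50 (3.48, 3.73) and LRX1 at 2.53 ± 0.32 (2.90, 2.02), and the extensins EXT6 (AT2G24980) (3.49 ± 0.42) and EXT10 (AT5G06640) (3.29 ± 0.39) rose alike. The root hair list had adjusted p = 0.029 with an estimated correlation and medians of 2.23 in A and 0.49 in B. The morning clock genes LHY (AT1G01060) (−1.40 ± 0.29 [−2.08, −0.41]) and CCA1 (AT2G46830) (−0.85 ± 0.21 [−1.38, −0.13]) fell and the evening genes PRR5 (1.23 ± 0.19 [1.44, 1.02]) and GI (AT1G22770) (0.83 ± 0.15 [1.02, 0.65]) rose, among 4 of 10 clock genes up and 3 down. Iron genes rose in 4 of 21 and fell in 1, with S8H at 3.02 ± 0.58 (3.42, 1.5) and the ferric reductase gene FRO2 (AT1G01580) at 1.77 ± 0.42 (2.69, 0.16), and camera's adjusted p of 0.0378 became adjusted p = 0.666 with an estimated correlation. CYP81D11 (−3.12 ± 0.29 [−3.07, −3.35]), the glutathione transferase gene GSTU25 (AT1G17180) (−2.12 ± 0.29) and the nitrilase gene NIT2 (AT3G44300) (−2.03 ± 0.29) fell in both experiments. PR1 had −0.84 ± 0.86 (−2.4, 4.37; adjusted p = 0.594). In all 923 genes were higher and 506 lower (2269 and 1887 in A, 674 and 735 in B). Of 485 genes called in both experiments 179 had the same direction and 306 the opposite, and 3341 genes differed between A and B. The count was 412 without replicate A2, 589 without A1 and 755 in a fit of the compared libraries alone.

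The interaction asked which genes responded to SynCom differently at low and at high Pi. AT5G20790 (5.40 ± 0.86), the organic cation transporter gene OCT1 (AT1G73220) (5.07 ± 0.73 [5.39, 5.58]) and PECP1 (5.11 ± 1 [5.85, 5.27]) had the largest positive values, with SPX1 at 3.26 ± 0.35 (3.82, 2.91) and SQD2 at 2.83 ± 0.28 (3.16, 2.41). Pi signalling and transport had 9 of 18 genes more positive at low Pi (9 adjusted over the list alone), scavenging 10 of 17 (12) and lipid remodelling 9 of 11 (9), with adjusted p = 0.0116, 0.0586 and 0.000325 with an estimated correlation. Glucosinolate genes followed in 16 of 19 (18 adjusted over the list alone), with BCAT4 at 3.03 ± 0.52 (2.94, 2.55) and CYP79F1 at 3.76 ± 0.88, though with an estimated correlation adjusted p = 0.135. Iron genes were more negative at low Pi in 9 of 21 (adjusted p = 0.247 with an estimated correlation), for example BHLH100 (−4.03 ± 0.73 [−4.50, −0.42]) and its relative PYE (AT3G47640) (−1.06 ± 0.19 [−1.33, −0.74]). The flavonoid regulator GL3 (AT5G41315) had 2.54 ± 0.54 (2.63, 2.21) and PRR5 −1.38 ± 0.27 (−1.19, −1.59). In all 865 genes were more positive and 1064 more negative at low Pi. Of 348 genes called in both experiments 341 had the same direction, and across genes the values of A and B correlated with r = 0.48. Between A and B 57 genes differed, against 5303 and 3341 for the 2 SynCom effects behind the interaction. A difference of effects has a larger error, so the smaller count does not by itself show that the experiments were more alike. The count was 749, 879 and 993 without replicates B1, A2 and B2.

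In phf1 at low Pi, PHF1 was lower than in Col-0 (−0.58 ± 0.10 [−0.64, −0.53]), PHR1 had −0.18 ± 0.08 and PHL1 −0.34 ± 0.16 (adjusted p = 0.182 and 0.21). Pi starvation genes were higher than in the wild type over 24 libraries each. The transporter PHT1;2 (AT5G43370), whose reads may overlap with those of near-identical copies, had 2.39 ± 0.22, PHT1;4 1.18 ± 0.16 (1.53, 0.59), SPX1 1.08 ± 0.16 (1.55, 0.60), PECP1 1.77 ± 0.23, SQD2 0.90 ± 0.13 (1.27, 0.44) and MGD2 (AT5G20410), a galactolipid synthase, 1.11 ± 0.16 (1.67, 0.30). The lists had 13 of 18, 13 of 17 and 7 of 11 genes higher (15, 14 and 8 adjusted over the list alone) and 1 scavenging gene lower, with adjusted p = 0.000161, 0.0112 and 0.0112 with an estimated correlation. Glucosinolate genes were higher in 7 of 19 (UGT74C1 (AT2G31790), a thiohydroximate glucosyltransferase, 0.66 ± 0.14 [0.64, 0.5]) and flavonoid genes in 5 of 14 (CHS, 0.74 ± 0.21 [1.53, −0.10]), with adjusted p = 0.392 and adjusted p = 0.265 with an estimated correlation. An elongation factor EF1α copy, AT1G07920, was 2.55 ± 0.13 higher (2.68, 2.4), and CRK4 (AT3G45860), a receptor-like kinase gene, lower (−1.34 ± 0.34 [−1.03, −1.26]). PR1 had −1.13 ± 0.56 (adjusted p = 0.234). In all 594 genes were higher and 422 lower (1531 and 1552 in A, 345 and 215 in B), and 702 differed between the experiments. The count was 143 without replicate A1, 332 without A2 and 610 without B2.

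At high Pi PHF1 had 0.10 ± 0.11 in phf1 against Col-0 (−0.05, 0.25, adjusted p = 0.668), PHR1 −0.14 ± 0.08 and PHL1 0.17 ± 0.16 (0.36, −0.1). Even so the mutant expressed Pi starvation genes that were low in the wild type. AT4 had 317 ± 160 CPM against 6.79 ± 4.16 (log2 fold change 5.57 ± 0.27 [6.05, 5.04]; n = 24 each), IPS1 9.73 ± 4.83 against 0.0785 ± 0.178, while SPX1 was 2.56 ± 0.18 higher, GDPD1 (AT3G02040), a glycerophosphodiesterase, 1.28 ± 0.14 and PLDZ2 1.53 ± 0.19 (1.66, 1.44). PAP10 (AT2G16430), a secreted acid phosphatase, was lower (−1.38 ± 0.17 [−1.54, −1.24]), as was the potassium channel gene SKOR (AT3G02850) (−0.96 ± 0.21 [−0.93, −1.02]). Of Pi signalling and transport genes 14 of 18 were higher (14 adjusted over the list alone; adjusted p = 1.97e-06 with an estimated correlation). Scavenging had 9 of 17 higher and 1 lower and lipid remodelling 6 of 11 higher (10 and 7 adjusted over the list alone), with adjusted p = 0.0678 and adjusted p = 0.141 with an estimated correlation. Cell division genes were higher in 2 of 13 (9 adjusted over the list alone), such as the kinase gene CDKB2;2 (AT1G20930) (0.46 ± 0.12 [0.59, 0.36]), and adjusted p = 0.3 with an estimated correlation. In all 512 genes were higher and 146 lower (263 and 38 in A, 725 and 624 in B), and 10 differed between experiments. Leaving out replicates B2, A2, B1 and A1 gave 212, 228, 300 and 357 genes, leaving out the 4 libraries at odds with their labels, 2 of them here as phf1, gave 887, and leaving out the 6 in doubt, which adds 1 here as Col-0, gave 1060.

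In the phr1 phl1 mutant at low Pi, PHR1 was lower than in Col-0 (−1.18 ± 0.09 [−1.10, −1.26]), PHL1 higher (2.09 ± 0.15 [2.51, 1.60]) and PHF1 lower (−0.95 ± 0.10). Pi starvation genes were lower together, with IPS1 at −2.66 ± 0.31 (−3.13, −2.28), PHT1;2 at −3.69 ± 0.38, SPX1 at −1.03 ± 0.16, the ribonuclease gene RNS1 (AT2G02990) at −2.39 ± 0.30, PAP10 at −1.67 ± 0.17 and NPC4 at −2.93 ± 0.22. MGD2 was higher (0.99 ± 0.16 [0.96, 0.95]). PHO2 (AT2G33770), the ubiquitin conjugase that miR399 represses, was 2.30 ± 0.15 higher (2.35, 2.30), at 850 ± 219 against 180 ± 130 CPM (n = 24). Of Pi signalling and transport genes 17 of 18 were lower (17 adjusted over the list alone; adjusted p = 0.00751 with an estimated correlation). Of scavenging genes 9 were lower of 17 (9; adjusted p = 0.259 with an estimated correlation). Of lipid genes 3 were higher and 4 lower of 11 (3 and 5; adjusted p = 0.611 with an estimated correlation). All 11 root hair genes were lower, such as the NADPH oxidase gene RBOHC (AT5G51060) (−0.93 ± 0.18 [−1.47, −0.41]). So were 9 of 13 sulfate genes (APR1, −0.95 ± 0.20) and 10 of 27 jasmonate genes (the repressor JAZ3 (AT3G17860), −0.48 ± 0.09). Adjusted p for these 3 lists was 0.135, 0.28 and 0.489 with an estimated correlation. Photosynthesis genes were higher in 14 of 19 (LHCB1.3 (AT1G29930), a light-harvesting protein, 0.47 ± 0.09 [0.66, 0.31]), with a median of 0.52 in A and 0.08 in B and adjusted p = 0.409 with an estimated correlation. SA genes were lower in 6 of 25, among them WRKY54 (−0.87 ± 0.18), and the list's adjusted p was 0.819 with an estimated correlation. PR1 had 0.20 ± 0.55 (−0.04, 0.27, adjusted p = 0.831). AT1G07920 was higher here too. In all 2669 genes were higher and 2482 lower, and only 56 and 393 of these changed by a log2 of 1 or more (2790 and 2666 called in A, 1700 and 1528 in B, 1855 different between A and B). The count was 3131 without replicate A2 and 3382 without A1.

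At high Pi PHR1 stood at −1.2 ± 0.08 in phr1 phl1 (−1.2, −1.23), PHL1 at 2.11 ± 0.16 (2.64, 1.48) and PHF1 at 0.14 ± 0.11 (adjusted p = 0.498). Here some Pi genes were higher than in Col-0, with IPS1 at 3.2 ± 1.67 against 0.0785 ± 0.178 CPM (n = 24), AT4 1.5 ± 0.26 higher (1.98, 0.92), PHT1;4 0.76 ± 0.20 and MGD2 1.13 ± 0.20 (1.61, 0.63), while PAP10 was lower (−1.56 ± 0.17 [−1.57, −1.68]). The 3 Pi lists had 3 of 18, 3 of 17 and 3 of 11 genes higher (6, 4 and 5 adjusted over the list alone) and 1 scavenging gene lower, with adjusted p = 0.698 for signalling and transport and adjusted p = 0.598 for lipids with an estimated correlation. Cell division genes were higher in 7 of 13 (11 adjusted over the list alone), such as CDKB1;1 (AT3G54180), a mitotic kinase gene (0.66 ± 0.17 [0.42, 1.01]). Higher as well were 4 of 21 iron genes, such as IMA2 (1.62 ± 0.37 [1.45, 1.8]), with adjusted p = 0.148 and adjusted p = 0.418 with an estimated correlation. JAZ3 was lower (−0.47 ± 0.09), as was COR413IM1 (AT1G29395), a cold-regulated chloroplast envelope gene (−0.95 ± 0.18 [−0.78, −1.13]). PR1 had 1.04 ± 0.57 (adjusted p = 0.298). In all 353 genes were higher and 195 lower (121 and 57 in A, 521 and 565 in B), and 0 differed between experiments by edgeR's test. Without replicates B2, A2, B1 and A1 the count was 40, 102, 118 and 331, and it was 31 with no experiment term.

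**Figure D4:**
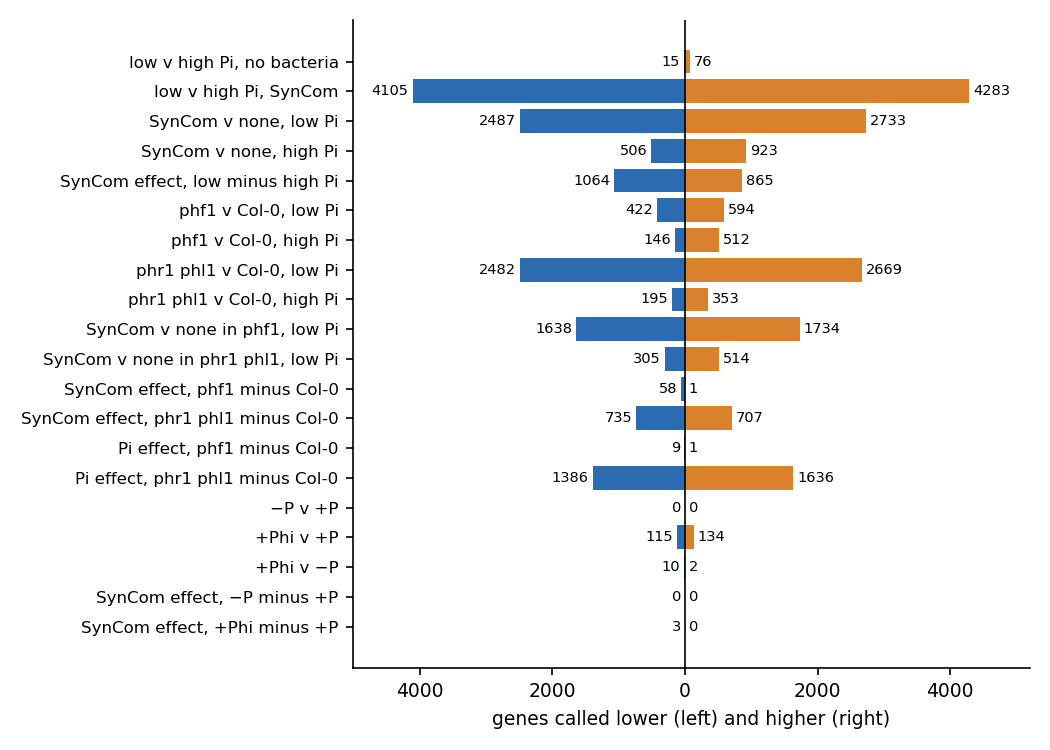
Genes called higher (bars to the right) and lower (bars to the left) in each of the 20 comparisons on a linear axis, with the counts printed. Low against high Pi gave 4283 higher and 4105 lower genes in Col-0 with SynCom and 76 and 15 without bacteria.

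In phf1 at low Pi, SynCom raised Pi genes by less than in Col-0. SPX1 rose by 1.23 ± 0.22 (1.07, 1.48), PHT1;2 by 2.41 ± 0.28, SQD2 by 1.53 ± 0.19 (1.40, 1.65) and NPC4 by 1.68 ± 0.23, and WRKY75 fell by 1.5 ± 0.22. The Pi lists had 16 of 18, 15 of 17 and 9 of 11 genes up (16, 16 and 9 adjusted over the list alone), with adjusted p = 0.00924, 0.00164 and 0.0132 with an estimated correlation. Glucosinolate genes all rose in the pooled fit (19 of 19; BCAT4, 2.21 ± 0.35 [0.91, 3.76]), with a median of 0.17 in A and 2.45 in B, 18 of them different between A and B and adjusted p = 0.0928 with an estimated correlation. Root hair genes rose in 9 of 11 (PRP3 (AT3G62680), 1.94 ± 0.28 [1.74, 1.99], adjusted p = 0.0721 with an estimated correlation) and FLA6 (AT2G20520), which encodes an arabinogalactan protein, rose by 3.20 ± 0.38. Iron genes fell in 11 of 21 and rose in 2, with BHLH39 (AT3G56980) at −2.97 ± 0.36 (−3.63, −1.15), and PYE at −1.16 ± 0.15 (−1.55, −0.74; adjusted p = 0.178 for the list with an estimated correlation). PR1 had 0.52 ± 0.84 (−1.33, 5.04). In all 1734 genes were higher and 1638 lower (2011 and 1698 in A, 3130 and 3287 in B). Of 1478 genes called in both experiments 741 had the same and 737 the opposite direction, and 6101 differed between A and B. The count was 2060 without replicate B2 and 2179 without B1.

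In phr1 phl1 at low Pi, the response to SynCom included jasmonate genes. The repressor JAZ9 (AT1G70700) rose by 1.13 ± 0.18 (1.2, 0.90), MYC2 by 0.90 ± 0.17 (0.60, 1.18), the jasmonate catabolism gene JRG21 (AT3G55970) by 3.25 ± 0.65 (1.26, 5.07) and the transcription factor gene NAC019 (AT1G52890) by 2.76 ± 0.59 (1.26, 4). Jasmonate genes rose in 16 of 27 (21 adjusted over the list alone; medians 0.44 and 1.66; adjusted p = 0.0578 with an estimated correlation). FRK1 rose by 1.79 ± 0.38 (1.18, 3.06) and the tryptophan-metabolising P450 gene CYP79B3 (AT2G22330) by 0.99 ± 0.17 (0.62, 1.27) among 5 of 24 pattern-triggered immunity genes (adjusted p = 0.0706 with an estimated correlation). Iron genes fell in 9 of 21 (adjusted p = 0.0453 with an estimated correlation), with BHLH38 at −4.41 ± 0.56 (−4.85, −1.21), but the list's median was −1.2 in A and 0 in B. SA genes rose in 6 of 25 (18 adjusted over the list alone), including the regulator CBP60G (AT5G26920) (0.90 ± 0.23 [0.81, 1.08]) and PR1 (3.14 ± 0.86 [−0.07, 7.20], adjusted p = 0.0165), with adjusted p = 0.387 with an estimated correlation. Glucosinolate genes rose in 6 of 19 (medians −0.13 and 1.44), with adjusted p = 0.238 with an estimated correlation. Of Pi signalling and transport genes 5 of 18 rose (SPX1, 0.84 ± 0.23 [0.29, 1.45]; IPS1, 2.41 ± 0.50), of scavenging genes 1 of 17 and of lipid genes 1 of 11 (11, 2 and 2 adjusted over the list alone), the sulfolipid gene SQD1 (AT4G33030) (0.71 ± 0.19 [−0.12, 1.5]), with adjusted p = 0.15 for the first list with an estimated correlation. In all 514 genes were higher and 305 lower (1040 and 615 in A, 1361 and 1356 in B). Of 373 genes called in both experiments 186 had the same direction, and 3083 differed between A and B. The count was 428, 493 and 507 without replicates B1, B2 and A2.

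The tests of the difference put these genotypes side by side with Col-0. The log2 fold change to SynCom at low Pi was lower in phf1 than in Col-0 for PHT1;2 (−3.19 ± 0.44 [−4.77, −2.20]), IPS1 (−3.35 ± 0.49 [−3.97, −3.49]), SPX1 (−2.00 ± 0.31 [−2.79, −1.31]), PECP1 (−3.02 ± 0.46 [−3.66, −2.44]), PAP14 (AT2G46880), an acid phosphatase (−4.53 ± 0.74 [−3.63, −4.74]), MGD3 (−2.54 ± 0.42 [−3.38, −1.5]) and NPC4 (−2.11 ± 0.33). Of the Pi lists 11 of 18, 10 of 17 and 6 of 11 genes were lower (16, 14 and 9 adjusted over the list alone), with adjusted p = 3.57e-09, 1.97e-06 and 1.97e-06 with an estimated correlation. In all 58 differences were negative, a lower log2 fold change in the mutant, and 1 was positive. PR1 (−1.53 ± 1.12 [0.19, −1.08]) and CYP79F1 (−0.48 ± 0.72 [−1.33, 1.59]) did not pass. The count was 1 and 67 in A, 0 and 10 in B, and 7, 31 and 39 in all without replicates A1, A2 and B1.

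For phr1 phl1 the same test gave lower log2 fold changes to SynCom for SPX1 (−2.4 ± 0.32 [−3.57, −1.33]), the Pi exporter homologue PHO1;H1 (AT1G68740) (−3.26 ± 0.47 [−3.14, −3.26]), PECP1 (−4.80 ± 0.52 [−5.75, −3.26]), MGD3 (−4.69 ± 0.46 [−5.36, −3.61]) and SQD2 (−2.51 ± 0.27 [−3.36, −1.59]). The Pi lists had 11 of 18 genes lower and 1 higher, 12 of 17 lower and 9 of 11 lower (13, 14 and 9 lower adjusted over the list alone), with adjusted p = 0.0107, 0.00125 and 4.79e-05 with an estimated correlation. Lower too were those of flavonoid genes in 4 of 14 (GL3, −1.84 ± 0.49 [−2.59, −0.98]), glucosinolate genes in 4 of 19 (the regulator MYB28 (AT5G61420), −1.18 ± 0.37 [−1.67, −0.88]), root hair genes in 6 of 11 (RBOHC, −1.3 ± 0.36 [−1.31, −0.89]) and sulfate genes in 4 of 13, with adjusted p = 0.135, 0.413, 0.276 and 0.221 with an estimated correlation. Higher log2 fold changes than in Col-0 appeared for JRG21 (3.91 ± 0.85 [2.71, 3.80]) and the monoterpene hydroxylase gene CYP76C2 (AT2G45570) (3.49 ± 0.86 [2.77, 5.93]). In all 707 differences were positive and 735 negative, whichever way the genes moved in Col-0 (966 and 1007 in A, 218 and 165 in B), and 36 differed between experiments. The count was 335 without replicate A2 and 561 without A1.

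With SynCom present, the log2 fold change to low Pi was lower in phf1 than in Col-0 for AT4 (−4.65 ± 0.47 [−4.97, −4.21]), IPS1 (−8.45 ± 0.92), SPX1 (−2.15 ± 0.33 [−2.37, −1.93]), PHT1;2 (−3.69 ± 0.62 [−4.16, −3.05]) and OCT1 (−2.99 ± 0.63 [−3.59, −2.27]). Since IPS1 had almost no counts in Col-0 at high Pi with SynCom, the size of its difference depends on that floor. In all 9 differences were negative, and the 1 positive one was that of AT3G13980, without a known function (1.08 ± 0.22 [1.11, 1.03]). Of Pi signalling and transport genes 5 of 18 were lower (10 adjusted over the list alone; adjusted p = 0.000325 with an estimated correlation). SA genes had 0 of 25 called by edgeR but 20 lower when adjusted over the list alone, as WRKY54 at −1.2 ± 0.35 (−0.33, −1.94; adjusted p = 0.302), and adjusted p = 0.135 with an estimated correlation. The count was 4 without replicate A2 and 5 without B1.

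The same test for phr1 phl1 gave differences of −9.88 ± 0.94 for IPS1 (−10.35, −9.91), −3.72 ± 0.48 for AT4, −2.60 ± 0.34 for SPX1 (−3.05, −2.15), −2.47 ± 0.38 for PAP17, −3.94 ± 0.59 for MGD3 and −4.47 ± 0.51 for NPC4 (−4.62, −4.45). The size of the IPS1 value again depends on the near absence of its counts in Col-0 at high Pi with SynCom. Differences were negative for 13 of 18, 10 of 17 and 7 of 11 genes of the Pi lists (14, 11 and 8 adjusted over the list alone), with adjusted p = 0.0112, 0.276 and 0.0359 with an estimated correlation. They were also negative for 7 of 13 sulfate genes (LSU2 (AT5G24660), a sulfur deprivation marker, −2.62 ± 0.59 [−3.60, −1.57]), 7 of 11 root hair genes (RHD6, −2.07 ± 0.41 [−2.30, −1.75]), 7 of 19 glucosinolate genes and 5 of 25 SA genes (WRKY54, −1.61 ± 0.35 [−1.47, −1.48]). For photosynthesis genes the differences were positive in 15 of 19 (LHCB1.3, 0.76 ± 0.18). The camera calls of the sulfate, root hair, glucosinolate, SA and photosynthesis lists were lost with an estimated correlation (adjusted p = 0.242, 0.276, 0.409, 0.701 and 0.3). In all 1636 differences were positive and 1386 negative, whichever way the genes moved in Col-0 (2203 and 1974 in A, 212 and 279 in B), and 5 differed between experiments. The count was 981, 997 and 1621 without replicates A2, A1 and B2.

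The pre-treatments asked whether the Pi status of the first week still showed after 12 days. Between −P and +P in Col-0, 0 genes were called by edgeR and by limma-voom and 27 by DESeq2, with 1889 genes at an unadjusted p under 0.05 (n = 16 libraries each). SPX1 had −0.20 ± 0.21 (−0.26, −0.05), PHT1;4 −0.03 ± 0.23 and AT4 −0.73 ± 0.31 (adjusted p = 0.439). Within experiment B 13 genes were higher and 30 lower, and 0 were called in A.

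Seedlings from +Phi had lower AT4 (−1.05 ± 0.30 [−0.75, −1.16], adjusted p = 0.0493) and lower PAP12 (AT2G27190), an acid phosphatase (−0.36 ± 0.10 [−0.35, −0.32]), than those from +P. SPX1 just missed the threshold at −0.75 ± 0.21 (−0.64, −0.72; adjusted p = 0.0504). Of the Pi lists 1 of 18, 1 of 17 and 0 of 11 genes were lower by edgeR (3, 4 and 3 adjusted over the list alone; adjusted p = 0.502, 0.502 and 0.387 with an estimated correlation). Higher after +Phi were the P450 gene CYP71A20 (AT4G13310) (1.39 ± 0.27 [1.83, 1.02]), the transporter gene ABCG15 (AT3G21090) (0.88 ± 0.17 [1.23, 0.53]) and PRR5 (0.63 ± 0.16 [0.66, 0.54]). In all 134 genes were higher and 115 lower (314 and 149 in A, 332 and 344 in B), and 168 differed between experiments. The count rested on few libraries, at 0 without replicate A1, 5 without B1, 56 without A2, 54 without the 6 libraries in doubt and 7 in a fit of the compared libraries alone.

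Against −P, seedlings from +Phi had 2 genes higher and 10 lower. FRUCT5 (AT1G55120), an invertase family gene, was lower (−0.78 ± 0.12 [−0.88, −0.72], adjusted p = 2.02e-05), as was the abscisic acid exporter gene ABCG25 (AT1G71960) (−0.58 ± 0.11 [−0.61, −0.52]), and the cuticle regulator MYB16 (AT5G15310) was higher (0.63 ± 0.14 [0.66, 0.59]). Lipid remodelling genes had 0 of 11 called by edgeR (6 lower adjusted over the list alone), with SQD2 at −0.51 ± 0.17 (−0.59, −0.43; adjusted p = 0.216) and adjusted p = 0.124 with an estimated correlation. In experiment A 3 genes were higher and 5 lower, in B 63 were higher and 224 lower, and the count was 5 with the replicate block and 1, 3, 4 and 6 without replicates A1, A2, B2 and B1.

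Whether the pre-treatment changed the response of Col-0 to SynCom at low Pi was tested with 4 libraries per group. After −P against +P 0 genes differed by edgeR, DESeq2 or limma-voom, with 592 at an unadjusted p under 0.05, and the 5 tested heat shock genes had a median of 1.11 (1.37, 1.37), a camera call lost at adjusted p = 0.247 with an estimated correlation. After +Phi against +P 3 genes had a lower log2 fold change, among them SAL2 (AT5G64000), a phosphatase gene of the SAL family (−2.10 ± 0.42 [−1.90, −2.31], adjusted p = 0.0133), and AT3G03790 (−1.66 ± 0.31 [−2.21, −1]). The third, the haem oxygenase gene HO4 (AT1G58300) (adjusted p = 0.013), was chosen after its values were seen and had no counts in the +P libraries without bacteria. DESeq2 called 9 genes and limma-voom 3. Lipid remodelling genes had 0 of 11 called by edgeR (6 lower adjusted over the list alone; medians −1.73 in A and −0.27 in B; adjusted p = 0.0112 with an estimated correlation), with SQD2 at −1.78 ± 0.47 (−2.59, −0.79; adjusted p = 0.169). SA genes had 0 of 25 called (15 lower adjusted over the list alone; medians −0.68 and −2.39; adjusted p = 0.12 with an estimated correlation), with WRKY54 at −2.19 ± 0.59 (−1.51, −2.97). The count was 0 without replicate A1 and 1 without the 4 libraries at odds with their labels, of which the library labelled Col-0, +Phi, low Pi, no bacteria, A1 is in this comparison.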

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

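The tests of an exchange of bacteria labels and of the phf1 marker, and the fits without 4 or 6 libraries, were chosen after the results were seen. The other tests were written before the value that each of them measures was known.

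In 4 measures of 36 groups, tests of a single library far from the other 3 of its group found 7 such values in 6 libraries, where chance gives 7.2 values. The Pi starvation index stood apart at 0.02 in Col-0, +Phi, low Pi, no bacteria, A2 (next −1.19) and at 0.12 in phf1, −P, high Pi, SynCom, A1 (next −0.83). In both groups the other library of experiment A is one whose PHR1 to PHL1 ratio goes against its label. PHR1 was low, in log2 CPM, in phr1 phl1, −P, low Pi, SynCom, B2 (4.19, next 4.87) and in phf1, −P, high Pi, SynCom, A2 (5.75, next 6.05). PHL1 was high in the libraries labelled Col-0, +Phi, low Pi, no bacteria, A1 (6.11, next 4.17), phf1, −P, high Pi, SynCom, A2 (6.23, next 4.06) and phf1, +Phi, high Pi, SynCom, A1 (5.00, next 3.76).

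Effects that differed between groups by a test of the difference were those of SynCom between low and high Pi (1929 genes), between phf1 and Col-0 (59), between phr1 phl1 and Col-0 (1442) and between the +Phi and +P pre-treatments (3), and those of Pi with SynCom between phf1 and Col-0 (10) and between phr1 phl1 and Col-0 (3022). Glucosinolate genes such as BCAT4 and Pi genes such as SPX1 are in the first set. Between experiments A and B the effects differed in 273 genes for Pi without bacteria and 588 with SynCom, in 5303 and 3341 for SynCom in Col-0 at low and high Pi, in 6101 for SynCom in phf1 and in 3083 in phr1 phl1. The phf1 effects differed in 702 genes at low Pi and 10 at high Pi, and the phr1 phl1 effect in 1855 at low Pi. Among differences of effects, the experiments differed in 57 genes for SynCom by Pi, 4 and 36 for SynCom by phf1 and by phr1 phl1, 5 for Pi by phr1 phl1 and 11 for SynCom by +Phi. The pre-treatments differed in 168 genes for +Phi against +P and 25 for +Phi against −P.

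The first pattern weighed is the difference of the SynCom effect between A and B in Col-0 at low Pi, where 10 of 25 SA genes fell and 2 rose in A and 18 rose and 1 fell in B (PR1, −1.52 in A, adjusted p = 0.032 there, and 6.11 in B) while Pi genes such as SPX1 rose in both. Bacteria labels exchanged in one experiment would turn the effects over, but the fold changes of A and B correlated across genes with r = 0.25, and genes are not independent replicates. Without the 6 libraries in doubt 6476 genes differed, against 5303 with them. Thinning 24 libraries to 2.48 M counts left the difference of the SA list at −2.66 (SE 0.56), from −2.94 (SE 0.56). Other differences between the experiments, such as the plants' state without bacteria, cannot be told apart from one another because experiment is a batch here, and no biological explanation was tested.

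The second pattern is the 4 libraries of experiment A whose ratio of PHR1 to PHL1 goes against their labels, in the 2 phf1 libraries through PHL1 alone. For the libraries labelled Col-0, +Phi, low Pi, no bacteria, A1 and phr1 phl1, +P, high Pi, SynCom, A1 a candidate explanation is an exchange, since 2 of the 2 were nearest, among 12 profiles of experiment A, to the profile of the other's label (r = 0.96 and 0.969, against 0.847 and 0.815 for their own, over 2000 genes that are not independent). Of 67 libraries of experiment A not in doubt 53 were nearest to the profile of their own label and 55 to one of their own genotype, so a nearest profile can be wrong. The way from the label's profile to the other genotype's, at the label's own Pi and bacteria, was measured over 8 genes that part phr1 phl1 from Col-0. PHR1 and PHL1 changed enough in the pooled fits to meet the rule for such genes. The shares are therefore not independent of the levels that flagged the libraries, and they do not test the exchange. On this way the Col-0 library lay at 0.652 (SD of other libraries 0.186), which leaves a wrong genotype open, and the phr1 phl1 library at 1.16 (SD 0.162). The library labelled phf1, −P, high Pi, SynCom, A2 lay at 0.917 of the way to phr1 phl1 but held 17 counts (4.11 CPM) of AT5G35760, a gene that marks phf1 libraries here and reached 0.91 CPM in other phr1 phl1 libraries, so it is not wholly a phr1 phl1 library, and a mixture was not tested. The library labelled phf1, +Phi, high Pi, SynCom, A1 lay at 0.42 (SD 0.217) with 9 counts of the marker, and whether its genotype is wrong stays open.

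Other splits of the same libraries into arms of the same size, 100 drawn for each comparison, were counted with fits of the compared libraries alone. In 1 of 100 splits, the real one, as many genes were called for Pi with SynCom (8585 genes, highest other 1848), SynCom in Col-0 at low Pi (5555, 1859) and high Pi (755, 399), phf1 at low (1311, 22) and high Pi (773, 1), phr1 phl1 at low (4820, 23) and high Pi (692, 4) and SynCom in phf1 (3357, 947). Chance is an unlikely source of these counts. The real split was also alone for +Phi against +P (7, 2) and against −P (7, 2), but each rests on 7 genes, so chance is not excluded. It was alone as well for SynCom by Pi (1593, 1157), by phf1 (34, 1) and by phr1 phl1 (1088, 326), and for Pi by phf1 (13, 0) and by phr1 phl1 (2668, 491). For these differences of effects, exchanging Pi or genotype labels broke up a main effect too. That can lower the counts of the other splits, so nothing is concluded from them. For Pi without bacteria (181, 224) and SynCom in phr1 phl1 (535, 1412), 2 of 100 splits called as many genes. Their share of 0.02, like the other shares, was not adjusted over the comparisons. In both, another split called more genes than the real one, so the evidence against chance is weak. SynCom by +Phi (2, 2) also had 2 of 100, but it rests on 2 genes. Exchanging pre-treatment labels broke up their main effect too, so nothing is concluded from it. The split with 224 genes kept 10 of 12 libraries of A and 8 of 12 of B under their own label. That with 1412 genes kept 10 of 12 libraries of A and 6 of 12 of B under their own label, so that it sets the SynCom effect of A against a mix in B, a structure of these samples. For −P against +P (0, 0) and SynCom by −P (0, 0) the real count was 0, which all 100 splits had to reach, so the splits test nothing there.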

How the results depend on the processing

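The fits without 4 or 6 libraries were chosen after the data were seen. The cause of the shifts below was not tested. Of 320 counts of genes under 16 alternatives, 210 stayed within 1.5 times the reported count and 110 moved. Of 156 index values, 146 kept direction and side of the threshold, 3 gained a call and 7 changed sign or became 0 with no call. Of 3552 values of genes named, 3253 kept both, 242 lost the call, 16 gained one, 31 changed sign with no call in either fit and 10 reversed.

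With no experiment term counts fell to 13 (Pi without bacteria), 609 (SynCom, high Pi), 897 (SynCom by Pi), 483 and 266 (phf1, low and high Pi), 31 (phr1 phl1, high Pi), 314 (SynCom in phr1 phl1), 33 and 759 (SynCom by phf1 and by phr1 phl1), 1310 (Pi by phr1 phl1), 17 (+Phi against +P), 5 (+Phi against −P) and 1 (SynCom by +Phi). Experiment A alone gave, for the counts that moved, 1452, 4156 and 932 for the first 3 of these, 3083 and 301 for phf1, 178 for phr1 phl1 at high Pi, 1655 for SynCom in phr1 phl1, 4 for Pi by phf1, 463 for +Phi against +P and 53 for SynCom by +Phi. Experiment B alone gave 5097 for Pi with SynCom, 560 and 1349 for phf1, 3228 and 1086 for phr1 phl1, 6417 and 2717 for SynCom in phf1 and phr1 phl1, 10, 383 and 491 for SynCom by phf1, by phr1 phl1 and Pi by phr1 phl1, 43, 676 and 287 for −P against +P, +Phi against +P and +Phi against −P, and 15 for SynCom by +Phi.

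With only the compared libraries in the fit the counts that moved were 181 (Pi without bacteria), 755 (SynCom, high Pi), 535 (SynCom in phr1 phl1), 34 (SynCom by phf1), 7 (+Phi against +P) and 7 (+Phi against −P). Limma-voom gave 1035 (Pi without bacteria), 2904 (SynCom by Pi), 1569 and 2055 (phf1), 1236 (phr1 phl1, high Pi), 643 (+Phi against +P) and 324 (+Phi against −P). DESeq2 gave 27 (−P against +P), 647, 23 and 9 (SynCom by +Phi). Without the 4 libraries Pi without bacteria had 187 genes and SynCom by +Phi 1, and without the 6 the counts were 179 (Pi without bacteria), 1060 (phf1, high Pi) and 54 (+Phi against +P). No filter gave 160 for +Phi against +P and 5 for +Phi against −P, which was 6 with other size factors, 6 with the stricter filter and 5 with the replicate block, which moved no other count.

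Leaving out a replicate gave 12 to 72 genes for Pi without bacteria, 5335 to 7834 for Pi with SynCom, 412 to 1749 for SynCom at high Pi, 749 to 1435 for SynCom by Pi, 143 to 1330 and 212 to 357 for phf1 at low and high Pi, 3131 to 4641 and 40 to 331 for phr1 phl1, 2060 to 3496 and 428 to 573 for SynCom in phf1 and phr1 phl1, 7 to 55 and 335 to 1032 for SynCom by phf1 and by phr1 phl1, 4 to 7 and 981 to 3768 for Pi by phf1 and by phr1 phl1, 0 to 1 for −P against +P, 0 to 295 for +Phi against +P, 1 to 6 for +Phi against −P and 0 to 2 for SynCom by +Phi. SynCom in Col-0 at low Pi and SynCom by −P moved under none of the alternatives run. Scaling by other size factors shifted the median of all genes by at most 0.01.

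The gene list tests passing fell from 160 to 30 with an estimated correlation and to 105 with fry. The index difference of SynCom in Col-0 at high Pi (0.03) was −0.01 with a prior count of 0.5, −0.07 in B alone and −0.01 to 0.12 without one replicate. That of SynCom in phr1 phl1 at low Pi (0.47) was −0.13 in A alone, 1.08 in B alone and 0.25 to 0.72 without one replicate, and passed in B alone (adjusted p = 0.0126), without A1 (0.62, adjusted p = 0.0371) and without A2 (0.72, adjusted p = 0.0488). At high Pi (−0.06) it was −0.12 to 0.02 without one replicate and −0.14 without the 4 or the 6 libraries. The variant without index genes failing the filter was not run, since all 25 passed. The 10 that reversed, with a call in the pooled fit or the alternative, did so in single experiments: in B alone APR3 (−0.02), BHLH38 (−0.84) and IMA2 (−0.97) for Pi without bacteria, BHLH100 (0.48) and IMA2 (2.28) for SynCom at low Pi, PR1 (4.37) for SynCom at high Pi and CHS (−0.10) for phf1 at low Pi, and in A alone PR1 (−1.52) for SynCom at low Pi and PR1 (−0.07) and SQD1 (−0.12) for SynCom in phr1 phl1. At the depth of these libraries the simulated test recovered 64.2% of 1.5-fold and 98.5% of 4-fold changes. Other depths, correlated genes and effects of experiment were not simulated.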

Other observations

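The test of reads shared between gene copies was chosen after the result was seen.

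AT1G07920, which encodes a copy of the elongation factor EF1α, was higher in both mutants than in Col-0 at both Pi levels. It averaged 32.4 ± 21.1 CPM in Col-0 (2.39 to 159), 189 ± 95.2 in phf1 and 175 ± 54.7 in phr1 phl1 (n = 48 each). Reads that moved from near-identical copies would lower those, unless the copies rose as well. The lowest log2 fold change of the other 3 copies over the 4 genotype comparisons was 0.12. AT1G07930 was itself called higher in all 4 comparisons (0.62 to 0.84). Together the 4 copies held 1450 ± 410 CPM in Col-0, 1870 ± 650 in phf1 and 1860 ± 462 in phr1 phl1. A move of reads on top of a rise of the copies is therefore not excluded. Without the 6 libraries in doubt 4 of the 4 comparisons called AT1G07920. A sequence difference between the lines and the reference genome was not tested, and no biological explanation was tested.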
